A study of Trichoderma harzianum
Globisporangium ultimum with 5 samples.

How the data were processed

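Gene expression was measured on one-colour NimbleGen arrays of a Trichoderma design, labelled with Cy3. The arrays carried RNA from dual cultures of the mycoparasitic fungus Trichoderma harzianum with the oomycete plant pathogen Pythium ultimum. Per the labels, plugs from 4-day colonies of both organisms were placed 2 cm from opposite borders of a plate and grown at 25 °C. Mycelium was collected where the colonies met, from 7 plates per condition, and 40 µg of RNA was supplied per 3-array set. The 5 arrays fell into 2 groups by the strain in the labels, with 2 arrays of the wild type T34 and 3 arrays of the nox1-overexpressing transformant Tnox5. The series text speaks of hybridization in triplicate, and 2 T34 arrays were analysed here. Replicate numbers follow the order of deposition and pair nothing. The labels do not say that arrays of a group came from separate cultures, so p-values measure only the spread between arrays, which may be technical. Neither labels nor files give a slide or batch shared by arrays, so no batch term was fitted.

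For each array the authors deposited 2 tables with 71364 rows, which are 35682 transcripts in 2 blocks per array. One table holds unnormalized intensity values per transcript and block, per the file headers an average over perfect-match probes, usually 5. The deposited files also give the coefficient of variation of those probes, a ratio of SD to mean. The other table holds intensity values on a linear scale that the authors normalized with RMA, per the submitters' processing notes, with the version not given in the sources used here. Mismatch values were 0 throughout. The deposited series value table holds intensity values of 5015 of the transcripts. Its values matched the geometric mean of the 2 unnormalized blocks within a relative difference of 1.04e-06, so their scale is linear, with no centring. How its transcripts were selected is not given in the sources used here. Its medians were 1383 and 1210 in the T34 arrays, and 1806, 1744 and 1650 in the Tnox5 arrays.

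Analysis here started from the RMA values. They were put on the log2 scale and the 2 blocks of an array were averaged per transcript. limma 3.58.1 in R 4.3.3 (lmFit and eBayes) was fitted to all 5 arrays, with the log2 change coded as Tnox5 minus T34. P-values were two-sided and adjusted by Benjamini-Hochberg over all 35682 transcripts. A transcript was called at an adjusted p under 0.05, and counts were also taken with at least a 2-fold change. The 2 against 3 arrays allow 10 splits, so an exact permutation test of a single value could not go below p = 0.1. The fit was tested on 10 simulated sets with the measured means and residual spread, in each of which 200 of 35682 transcripts were changed. It recovered 20.4% of transcripts changed 2-fold, 58.9% of those changed 4-fold and 0% of those changed 1.5-fold, with 0.6 false calls per set. Simulated transcripts were independent of each other, so recovery and false calls in the measured data may differ. The number of arrays limits the precision. No detection call was used here, so unnormalized intensities are given beside folds of dim transcripts.

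The files pair transcript IDs with no gene names, and 0 of the 35682 IDs matched the 14294 rows of the reference gene table for this species. The nox1 transcript and the gene lists fixed before the data were examined (NADPH oxidase, antioxidant defence, chitinases, glucanases, cellulases, proteases, secondary metabolism, transport and others) were therefore not analysed here. The named transcripts were, by a rule fixed before the data were examined, the 2 with the largest rise and the 2 with the largest fall among calls whose arrays did not overlap between groups. Transcripts were grouped by the code written in their ID. There are 10 short codes (T34, T78, T3K, T11 and others), some of whose IDs also carry an L number, and 2 codes of gene models, Trive1 and Triat1. Several IDs may stand for the same gene, which was not tested, so counts of transcripts are not counts of genes. Codes were used as written, and only T34 matches a strain name in the labels. For each code of at least 20 transcripts, called and uncalled transcripts were compared with Fisher's exact test, two-sided, and shifts were tested with limma's camera with a preset correlation of 0.01, with camera with an estimated correlation and with fry, each adjusted over the 12 codes. The camera step called a simulated shift of 0.1 in 10 of 10 sets and no shift in 0 of 10. Transcripts in these sets were drawn independently, so they cannot show how camera behaves when transcripts of a code are correlated. Scaffold numbers of gene models were read from the model names, and calls per scaffold were tested with the hypergeometric distribution, also with the brightness decile of the models taken into account.

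Alternatives fixed before the data were examined were the unnormalized values with quantile scaling, with median centring, or with normexp (offset 50) and quantile scaling; the series value table; a further quantile scaling of the RMA values; leaving out the dimmest 25% of transcripts; a trended robust variance prior; array weights; a stricter threshold of 0.01; median polish of the blocks; and leaving out each array in turn. Added after seeing the data were each block alone, the trended and the robust prior alone, transcripts with an unnormalized intensity of at least 200, the brightest 20% of transcripts, and the estimated correlation for the codes. The text does not use any other per-sample column.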

Results

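The series compared gene expression in dual culture with Pythium ultimum between Trichoderma harzianum T34 and its transformant Tnox5, which overexpresses nox1, an NADPH oxidase gene. NADPH oxidases produce reactive oxygen species. There were 2 T34 arrays and 3 Tnox5 arrays, each measuring 35682 transcripts. The median unnormalized intensity per array was 219 and 187 in T34 and 198, 175 and 175 in Tnox5. The files pair transcript IDs with no gene names, so the level of nox1 in each array, which would check the labels, was not analysed here.

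Arrays of a group resembled each other more than arrays of different groups. Across transcripts, the correlation of normalized log2 values was 0.994 between the T34 arrays and ranged from 0.995 to 0.996 among the Tnox5 arrays. Between the groups it ranged from 0.990 to 0.993. Transcripts are not independent replicates, so these values are descriptive.

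In Tnox5, 364 transcripts were higher and 72 were lower than in T34 at an adjusted p under 0.05 in limma. Of these, 287 were at least 2-fold higher and 54 at least 2-fold lower. The median change was 2.74-fold among the transcripts called higher and 2.52-fold among those called lower. On this normalized scale the median residual SD was 0.27 in decile 4 of unnormalized intensity and 0.041 in decile 10. In the unnormalized values with quantile scaling it was 0.059 and 0.073. Sizes of change, and so the 2-fold counts, may thus not be comparable between dim and bright transcripts. As single examples, log2 changes normalized and unnormalized were 1.28 and 2.56 in the bright L02T34P067R06281, and 5.38 and 1.98 in T78C20. In the normalized values, at least 8-fold rises were found in 44 of the called transcripts, and at least 4-fold falls in 12. These rises include T78C20 and L21T78P003R00240, described below, whose normalized changes give no reliable fold. The arrays of the groups did not overlap for any of the 436 called transcripts. They did not overlap for 35.4% of all transcripts, where chance gives 20%. Transcripts called higher made up 83.5% of the calls from the normalized values and 55.1% of the calls from the unnormalized values with quantile scaling, which called 3387 higher and 2756 lower.

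The number of calls depended on single arrays. It was 59 without T34 replicate 1, 122 without T34 replicate 2 and 15 without Tnox5 replicate 1. It was 0 in limma without Tnox5 replicate 2 or replicate 3, where 4633 and 4569 transcripts had an unadjusted p under 0.05. With all arrays 5666 transcripts had one.

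T78C20 showed the largest rise among the calls in the normalized values. Its normalized log2 intensity was 5.96 ± 0.32 (SD, n = 2) in T34 and 11.34 ± 0.11 (SD, n = 3) in Tnox5. The log2 change of T78C20 was 5.38 ± 0.17 (SE; limma, adjusted p = 0.00416). Another transcript with the T78 code, L21T78P003R00240, rose by 5.37 ± 0.24 on the log2 scale (SE; limma, adjusted p = 0.00521). Whether these 2 transcript IDs stand for separate genes was not tested. Both were dim in T34, with unnormalized intensities of 104 and 103, near the median of 104 in decile 3 of all transcripts, against 389 and 391 in Tnox5. Their normalized changes therefore give no reliable fold. In the unnormalized values with quantile scaling the rises were 3.93-fold for T78C20 and 3.95-fold for L21T78P003R00240, and 84 of the transcripts called higher rose further than T78C20 there. These folds rest on the same dim T34 values and are uncertain as well. T78C20 was no longer called without Tnox5 replicate 2 (limma, adjusted p = 0.0555) or replicate 3 (adjusted p = 0.0601). L21T78P003R00240 was not called without Tnox5 replicate 1, 2 or 3 (adjusted p = 0.0523, 0.0606 and 0.0642).

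**Figure D1:**
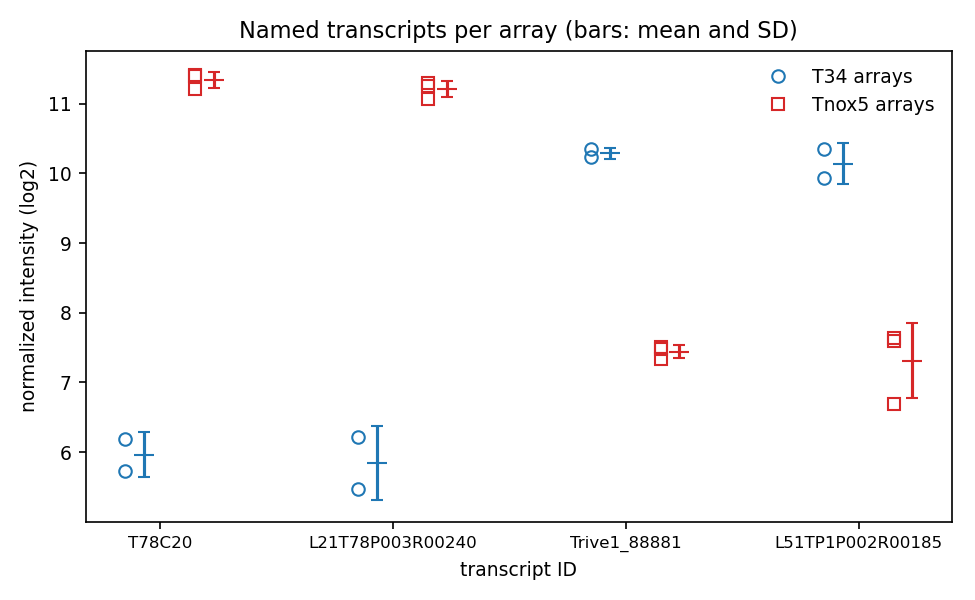
Normalized intensity (log2, vertical axis) of the 4 named transcripts in each T34 array (circles) and Tnox5 array (squares), with bars for the mean and SD of each group. The arrays of the groups do not overlap for any of the 4 transcripts, and T78C20 goes from a mean of 5.96 in T34 to 11.34 in Tnox5.

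The largest falls among the calls in the normalized values were those of Trive1_88881 and L51TP1P002R00185. Trive1_88881, a gene model on scaffold 12 by its model name, fell from 10.29 ± 0.08 (SD, n = 2) in T34 to 7.44 ± 0.09 (SD, n = 3) in Tnox5 on the log2 scale. Its log2 change was -2.85 ± 0.11 (SE; limma, adjusted p = 0.00416), and its unnormalized intensity went from 672 to 125, a 5.13-fold fall with quantile scaling. The Tnox5 level was dim, between the medians of 115 in decile 4 and 150 in decile 5, so the fold is uncertain. Trive1_88881 was no longer called without Tnox5 replicate 2 (limma, adjusted p = 0.0559) or replicate 3 (adjusted p = 0.0618). The log2 change of L51TP1P002R00185 was -2.83 ± 0.34 (SE; limma, adjusted p = 0.0393), and its unnormalized intensity went from 312 to 126, a similarly dim level. With quantile scaling the fall was 2.26-fold, and 41 of the transcripts called lower fell further there. It was not called when any 1 of the 5 arrays was left out, with adjusted p from 0.0747 to 0.215 in limma.

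The origin of the probe sets, as coded in the transcript IDs, set apart the transcripts with the code T34, the name of the wild-type strain. Of 3351 T34-coded transcripts, 153 were called higher and 10 lower in Tnox5. The odds of being called higher were 7.28 times those of other transcripts (Fisher's exact test, adjusted p = 1.25e-60 over the 12 codes). The odds ratio was 1.61 without Tnox5 replicate 1, where 14 transcripts in all were called higher (adjusted p = 0.869). T34-coded transcripts were also the brightest, with a median unnormalized intensity of 6123, and their odds ratio was 7.10 within the brightest 20% of transcripts, 3.72 among transcripts with an intensity of at least 200 and 4.23 in the series value table. Fisher's test treats transcripts as independent.

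Transcripts of the T78 and T3K codes were called higher more often than other transcripts as well, with 32 of 1021 and 21 of 740. Their odds ratios were 3.35 and 2.95 (Fisher's exact test, adjusted p = 1.00e-07 and 8.79e-05), and their median unnormalized intensities were 2260 and 4447. Of the T78-coded transcripts 6 were called lower, with an odds ratio of 3.10 that did not pass adjustment (Fisher's exact test, p = 0.0171, adjusted p = 0.102). Of 551 TH2-coded transcripts, 11 were called higher (adjusted p = 0.0457). Calls higher were rarer for the Triat1 gene models, with 10 of 11098 and an odds ratio of 0.062, and the Trive1 gene models, with 96 of 11638 and an odds ratio of 0.738 (adjusted p = 1.97e-43 and 0.0194). They were also rarer for the T53 code, with 2 of 1247, and the TP1 code, with 4 of 1424 (adjusted p = 0.00109 and 0.00357). In the unnormalized values with quantile scaling the Trive1 direction turned, with 1184 called higher and an odds ratio of 1.12 (Fisher's exact test, adjusted p = 0.00312), and TH2 did not pass (adjusted p = 0.10). Median unnormalized intensities were 112 for Triat1, 278 for Trive1, 134 for T53 and 139 for TP1. In the normalized values, brightness deciles 1 to 3 held no transcript called higher and decile 4 held 5, so dim codes had little room for calls. For codes other than T34, odds of calls were not compared within brightness, so differences in these odds cannot be told from brightness. Median log2 changes did differ between codes at like brightness. In decile 6 they were 0.43 for T3K, 0.18 for T78, -0.03 for Triat1 and -0.125 for T59, which was not tested. In the normalized values, calls lower were rarer for Triat1, with 9 transcripts (adjusted p = 0.00378), and differed for none of the other 11 codes. In the unnormalized values they were also rarer for T34-coded transcripts, with 174 of 3351 and an odds ratio of 0.631 (adjusted p = 4.87e-09), against 1.56 in the normalized values. There the odds of a call lower differed for 11 of the 12 codes, all except T78.

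**Figure D2:**
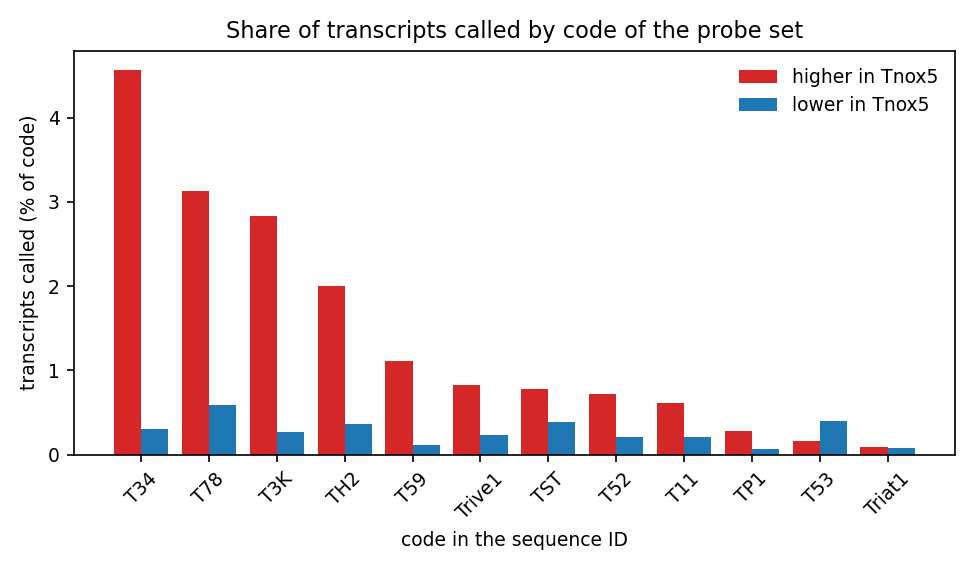
Percent of the transcripts of each code that were called higher (red bars) or lower (blue bars) in Tnox5 than in T34, with the code of the transcript ID on the horizontal axis. The T34 code has the highest share called higher, 4.57%, and Triat1 the lowest, 0.0901%.

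The T34-coded transcripts as a set lay above the others. Their median log2 change was 0.10, which was 0.12 above the median of all other transcripts (camera with the preset correlation, adjusted p = 2.03e-12). This call was lost with an estimated correlation (adjusted p = 0.336), which was estimated at 0.171 for this code. fry, which tests the set against no change and not against other transcripts, gave an adjusted p of 0.0845. In the normalized values, none of the other 11 codes passed in camera with the preset correlation over all transcripts, where adjusted p ranged from 0.208 to 0.682. From the unnormalized values with quantile scaling, TST and TP1 were called lower by this test (adjusted p = 0.0035 and 0.0126). With an estimated correlation neither passed there (camera, adjusted p = 0.0718 for each). The Triat1 models were called lower than the other transcripts in the series value table, by a median of -0.24 (adjusted p = 4.41e-08), with an intensity of at least 200, by -0.07 (adjusted p = 0.0175), and in the brightest 20%, by -0.14 (adjusted p = 9.64e-08). The Trive1 models were called lower in the brightest 20%, by -0.07 (adjusted p = 0.000619). Such falls were not particular to the gene models. In the brightest 20% the median log2 change was -0.182 for T11, -0.167 for TP1, -0.166 for T53, -0.156 for Triat1 and -0.072 for Trive1. It ranged from -0.110 for TST to -0.009 for T78 in the remaining codes except T34, where it was 0.073. T34-coded transcripts were 2633 of the 7137 there, so the shifts of the gene models against other transcripts are not separate from the T34 rise. The medians per code are each code's own change, and whether they are separate from that rise was not tested. Median changes were above 0 in 8 of 8 L-numbered sets of the T34 code, from 0.021 to 0.177, and in 2 of 17 such sets of other codes, where they ranged from -0.103 to 0.011. Of the 8 T34-coded sets, L05, L06 and L08 did not pass camera with the preset correlation (adjusted p = 0.0551, 0.507 and 0.501), and none passed with an estimated correlation (lowest adjusted p = 0.321). L05 held no called transcript. Of sets with other codes, T11 L13, T11 L22, T52 L19, T53 L14, T59 L20, TP1 L51, TP1 L54 and TST L56 were called lower. Their adjusted p ranged from 0.0159 to 0.0333 in camera with the preset correlation. None of them passed in camera with an estimated correlation (lowest adjusted p = 0.162). Each L-numbered set was tested only against other L-numbered transcripts of short codes. T34-coded transcripts are part of that background, so these lower calls are not separate from the T34 rise. Over all transcripts, the codes T11, T52, T53, T59, TP1 and TST did not pass (camera with the preset correlation, adjusted p from 0.208 to 0.296).

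**Figure D3:**
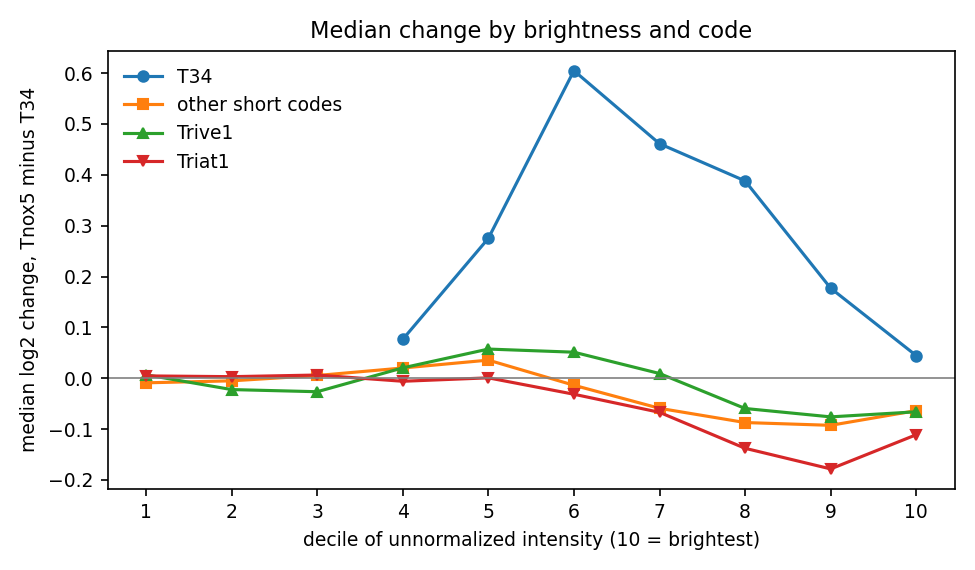
Median log2 change, Tnox5 minus T34, of T34-coded transcripts, of transcripts with other short codes and of the Trive1 and Triat1 gene models, by decile of unnormalized intensity, for points of at least 20 transcripts. T34-coded transcripts lie above the other 3 sets in every decile shown, with a median of 0.60 in decile 6 and 0.04 in decile 10. The changes are in the normalized values, so their sizes may not be comparable between deciles. Other short codes are pooled. Taken singly, TH2 (0.42) and T3K (0.38) lay above T34 (0.28) in decile 5, and TH2 and T59 did in decile 4. In deciles 6 to 10 T34 lay above each single code.

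The deposited versions of the measurements differed widely in how many transcripts they called, but little in direction for the calls from the normalized values. The share of calls that were higher differed as well. It was 83.5% in the normalized values, 55.1% in the unnormalized values with quantile scaling and 79.1% in the series value table. Of the 436 calls from the normalized values, 419 were also called from the unnormalized values with quantile scaling, 351 higher and 68 lower, and 6 had the opposite direction there. Across all transcripts, the log2 changes from the normalized and unnormalized values correlated with r = 0.706, and among the 436 calls with r = 0.834. The series value table held 14.1% of the transcripts and 355 of the called ones, with 301 higher and 54 lower. Its transcripts were 26.9% T34-coded, and their median log2 change was 0.34 there, against 0.16 for the same transcripts in the normalized values. Of its transcripts, 3119 were called higher and 824 lower from its own values, which are not scaled between arrays. In the unnormalized values as deposited, 82.7% of its transcripts were higher in Tnox5. Their selection is not known and may depend on the change, so shifts of codes within the series value table may reflect it.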

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

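Tests of each block alone, of the trended or the robust prior alone, of an intensity minimum of 200, of the brightest 20% of transcripts and of the estimated correlation for the codes were chosen after the results were seen. The counts of called transcripts changed with the version of the values and with single arrays. Against 364 higher and 72 lower, limma called 3387 and 2756 from the unnormalized values with quantile scaling, 4449 and 1044 with median centring, 3366 and 2815 after normexp, and 3119 and 824 from the series value table. The smallest adjusted p in limma was 7.72e-23 with median centring and 1.62e-290 in the series value table. Values this small from 5 arrays rest almost wholly on the shared variance prior, so these counts are not comparable with the others. A trended robust prior on the normalized values gave 2130 and 1599, and the trend alone 2059 and 1533. The intensity minimum of 200 gave 1133 and 500, and leaving out the dimmest 25% gave 133 lower. The first block alone gave 175 and 28, the second 156 and 26. A threshold of 0.01 left 79 and 13. Leaving out 1 array gave 0 to 117 higher and 0 to 5 lower, and the same counts with at least 2-fold; the fit then has fewer samples, and where T34 keeps 1 array it is assumed to vary like Tnox5. With at least a 2-fold change, 287 and 54 became 445 and 165 with quantile scaling, 686 and 123 with median centring, and 524 and 205 after normexp, and lower calls became 102 in the series value table, 148 with the trended robust prior and 149 with the trend alone. Blocks alone gave 175 and 28, and 156 and 26, and the 0.01 threshold 79 and 13. The cause was not tested except where observations below give a value. The robust prior alone, further quantile scaling and array weights kept the counts within 1.5 times. Median polish had to give the same counts, since the median of 2 blocks is their mean. T34-coded transcripts stayed above the others by 0.13 to 0.23 over quantile scaling, the series value table and the brightness filters, and by 0.11 to 0.13 with 1 array left out, past the threshold with the preset correlation; with an estimated correlation the 0.12 was not (adjusted p = 0.336). Their odds ratio for calls higher was 3.72 with the intensity minimum and 4.23 in the series value table, against 7.28, and ranged from 1.61 to 9.31 with 1 array left out; without Tnox5 replicate 2 or 3 there were no calls and no ratio. The 4 named transcripts kept their direction in all alternatives run on them, with adjusted p of at most 0.0601 for T78C20, 0.0642 for L21T78P003R00240, 0.0618 for Trive1_88881 and 0.300 for L51TP1P002R00185. Triat1 and Trive1 models gained calls as lower sets under some of these filters, and the TST and TP1 codes in the unnormalized values with quantile scaling. Under the brightness filters, shifts are tested here only for the T34, Triat1 and Trive1 codes. Alternatives for nox1 and the gene lists were not run, since the files pair IDs with no names. No paired analysis was possible because replicate numbers follow the order of deposition. Dim transcripts limit the folds: the median residual SD of normalized log2 values was 0.27 in decile 4 of intensity and 0.041 in decile 10.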

Other observations

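The scaffold tests, the contrasts between codes and probe sets, the calls within the brightest 20%, the trended robust prior on the unnormalized values, the trend and the robust option alone and the splits of the arrays were chosen after the results were seen. The quantile-scaled unnormalized values and the trended robust prior on the normalized values were alternatives fixed earlier, and their use as tests of an explanation was chosen afterwards. Calls among the 11638 Trive1 gene models were counted per scaffold, as numbered in the model names. On scaffold 29, 3 of 90 models were called lower in Tnox5, against 27 of all 11638, which did not pass adjustment over 278 tests of scaffold and direction (adjusted p = 0.159). From the unnormalized values, 5 of the 90 were called and at least 2-fold lower (adjusted p = 0.00816), but without the fold minimum 13 of the 90 were called lower (adjusted p = 1). The median log2 change of the 90 models was -0.12 in the normalized and -0.04 in the unnormalized values, at percentiles 0.04 and 0.03 of 10000 lists matched on brightness, which are not adjusted for the choice of this scaffold. All Trive1 rows carry a block name starting with ATRO and the Triat1 rows one starting with VIRENS, so the species behind these codes was left open.

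On scaffold 41, 4 of 18 models were called higher in Tnox5, against 96 of all 11638. Chance among the many scaffolds tested is argued against by an adjusted p of 0.00338 over 278 tests, which treats neighbouring models as independent. Brightness was tested by taking the expected calls of each scaffold from the brightness deciles of its models, and the adjusted p was 0.00447. The normalization was tested with the unnormalized values, where the same 4 and 8 in all of the 18 were called higher (adjusted p = 0.0268), although with at least a 2-fold change only 2 were (adjusted p = 0.966), and the median change of the 18 lay at percentile 94.1 of matched lists in the normalized values (11 above 0) and 99.7 in the unnormalized ones (15 above 0). A group of neighbouring genes that rises together in the transformant may be a candidate explanation; probes shared between related models were not tested.

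T34-coded transcripts shifted up in Tnox5 against other short codes, by 0.14 ± 0.02 (SE over arrays) in the brightest 20% of transcripts, with no overlap between the arrays of the groups. Brightness alone is argued against, since the difference was 0.26 ± 0.04 in decile 9 and 0.112 ± 0.010 in decile 10. A larger share of Trichoderma RNA in the Tnox5 samples would raise other bright, even probe sets alike, but T34-coded sets exceeded T3K-coded ones by 0.0753 ± 0.0047, which argues against it as the whole cause if the T3K-coded sets take their signal from Trichoderma RNA. Weaker hybridization of mismatched probes on the Tnox5 arrays may contribute, since among other short codes uneven probe sets (coefficient of variation over 1) differed from even ones (under 0.4) by -0.137 ± 0.040, and by -0.205 ± 0.010 in the unnormalized values with quantile scaling. In T34-coded sets this difference was 0.18 ± 0.06 in the normalized values and 0.0032 ± 0.0079, with overlapping arrays, in the unnormalized ones, and an effect of the strain on T34 genes stays open and untested.

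The unnormalized values gave 6143 calls and the normalized ones 436. Dim transcripts may lower the normalized count through the prior variance they share with bright ones. In the brightest 20% the unnormalized values gave 2421 calls and the normalized ones 92, but with a trended robust prior in both the ratio was 1.44, 2770 against 1924. A single prior for transcripts whose spread falls with brightness, as in the normalized values, is part of the same explanation and not a separate one. The trend alone raised the calls from the normalized values 8.24 times, to 3592, and the robust option alone gave 359. Over all transcripts, the unnormalized values still gave 1.82 times as many calls with a trended robust prior in both. Of the 10 splits of the 5 arrays into 2 and 3, 1 gave as many as 436 calls, the real one, and the highest other gave 0; 10 splits are too few for a share under 0.05.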
